A study of Arabidopsis thaliana with 6 samples.

How the data were processed

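RNA from shoots of Brassica oleracea var. alboglabra, the doubled haploid line A12dH, was hybridised to Affymetrix ATH1 arrays, whose probes were designed for Arabidopsis thaliana. The organism field of the sample records reads Arabidopsis thaliana, while their characteristics give Brassica oleracea and the series title calls the study a cross-species one. Total RNA was labelled with biotin, per the labels. The 6 arrays form 2 groups of 3, phosphate-starved (P-starved) and nutrient-replete (replete), numbered 1 to 3 in each group by their titles. The labels do not say whether the 3 samples of a group came from separate plants or harvests, so the p-values measure only the spread between these samples, which may be partly technical. How phosphate was withheld and for how long is not given in the sources used here.

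The deposited values are MAS5 signal, a linear probe set intensity, and MAS5 is the tool named in the submitters' processing notes. Its version, the probe set definition and any masking of probes are not given in the sources used here. The values bear out a linear scale: the 2% trimmed mean of every array, over the probe sets it lists, was 100. The arrays do not list the same probe sets. Both replicate 1 arrays list 22810, and the replicate 2 and 3 arrays of both groups list 19642 of these, so that 3168 are given for the replicate 1 arrays alone. Log2 signals correlated with r between 0.903 and 0.927 across probe sets among arrays that list the same probe sets, and between 0.608 and 0.633 otherwise. The 2 kinds of array are called processing sets below. Each set holds both groups, so the group difference can be measured within each of them.

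Each array was multiplied so that its 2% trimmed mean was 100, and log2(signal + 16) was taken. A difference on this scale understates the change of dim probe sets, and between 21.8% and 33.9% of the tested probe sets of an array lay under a signal of 16. No detection calls were used, and the number of arrays limits the precision. The 64 control probe sets were left out, which left 19578 probe sets with a value on all 6 arrays. P-starved and replete arrays were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a trend on mean level, group as the only term, two-sided tests and Benjamini-Hochberg adjustment at 0.05. Log2 differences are P-starved minus replete, with the standard error (SE) of this fit, and signals are means ± SD over 3 arrays of a group. Results are also given with the processing set as a block, for the replicate 1 arrays, and for the replicate 2 and 3 arrays.

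Probe sets were named through the platform's gene table, which lists 14016 of the 22810 probe sets. Of these, 13513 have 1 gene and 503 have several, and the other 8794 have no gene given here. Gene IDs of 13436 probe sets matched a table of Arabidopsis genes (TAIR10.1), from which symbols and loci were taken. Among the tested probe sets 11495 have 1 gene, which covers 11392 genes, and for lists the probe set of highest mean signal stood for its gene. Probes designed for Arabidopsis do not resolve the gene copies of Brassica, so each name stands for the Arabidopsis gene the probes were designed for. Coordinates are not given, because no genome build is named for the arrays.

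Before the data were examined, the group-only design, 24 gene lists with 437 members, the rule for named genes and most alternatives were fixed. Under that rule the 10 largest changes per direction past the threshold would be named, or, with none in a direction, the 5 smallest unadjusted p, given as values. From each list up to 4 genes with the smallest unadjusted p were to be named. Here all 4 are given for the ribosomal list, and at most 2 for each other fixed list, again those of smallest p among the genes measured. Only 65 members of the 24 lists were measured under a name on all arrays, which is what measured means for lists below. Of the lists, 8 had 3 or more measured genes and were tested, 11 had 1 or 2 and 5 had none. Some other members are listed on the replicate 1 arrays alone and were not tested. A further 8 lists were written after the gene table had been seen and before any group difference was computed, and were adjusted among themselves. A set of cytosolic ribosomal protein genes not on the fixed list was written after the result of that list was known. The processing-set block, the fits on the replicate 2 and 3 arrays alone, scaling over the shared probe sets and a second naming rule, 10 probe sets per direction from the blocked fit, were chosen after seeing the data. That second rule took the smallest p among the brighter 50% of the probe sets with 1 gene whose groups did not overlap in either processing set and differed the same way in both.

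Lists were tested with limma's camera with a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. Alternatives set beforehand were offsets of 4 and 64, only the brighter 50% of the probe sets, values as deposited, quantile normalization, scaling to a common 75th percentile, eBayes without trend or with robust settings, probe set types that can match several genes left out, the replicate number as a block, and each array left out in turn. RNA quality was compared with exact permutation tests on the 3' over 5' signal ratios of control genes. Arrays of the same number deviated from their group means together across probe sets, with r of 0.839 for replicate 1, 0.551 for replicate 2 and 0.530 for replicate 3. Arrays of different numbers within the second set did so almost as much (0.533 and 0.524), so this pairing is hard to tell from the split into processing sets.

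The fits were tested on simulated data that kept the measured means, set differences and residual spread of the 19578 probe sets, with 200 of them changed. The group-only fit recovered 4.5% of changes of 1 on the log2 scale, 6.0% of changes of 2 and 39.0% of changes of 3. The fit with the set as a block recovered 11.5%, 77.0% and 97.5% of them. The measured scale has a floor set by the added offset, so dim probe sets cannot fall this far. The simulated changes took no account of that floor, so these shares may be too high for lower values. In 100 simulated lists of 15 independent genes shifted by the ribosomal list's median, camera in the blocked fit had an unadjusted p under 0.05 in 96%, and in 7% of lists without a shift. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.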

Results

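The series measured shoot transcripts of Brassica oleracea under phosphate starvation or full nutrient supply, to find which genes respond to phosphate starvation in this crop by way of the probes of its relative Arabidopsis. There were 3 P-starved and 3 replete arrays. The median signal of the tested probe sets was 67.1 and 67.8 on the replete and P-starved replicate 1 arrays, and between 43.8 and 46.4 on the other 4 arrays. The first principal component held 71.9% of the variance, and all the low correlations between arrays lay between the 2 processing sets. Within the second set, 2 arrays of a group correlated with a mean r of 0.918 across probe sets and 2 arrays of different groups with 0.909.

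In P-starved shoots the expansin gene EXPA15 (AT2G03090), whose product loosens cell walls, had a signal of 454 ± 40.5 (SD, n = 3) against 210 ± 82.2 in replete shoots, a log2 difference of 1.12 ± 0.33 (SE). The cytochrome P450 gene AT3G44970 was measured at 59.0 ± 8.94 against 8.73 ± 5.77, with a log2 difference of 1.62 ± 0.44. Among the probe sets with lower values, ATSPS4F (AT4G10120), a sucrose phosphate synthase of sucrose synthesis, had 25.5 ± 29.5 against 125 ± 2.74, a log2 difference of -1.98 ± 0.59. AT2G25730 had 85.1 ± 14.5 against 219 ± 39.3, a difference of -1.21 ± 0.31. These genes were named as those with the smallest unadjusted p, and neither they nor any other probe set passed the threshold: limma called 0 higher and 0 lower of 19578, with a smallest adjusted p of 1.00. At an unadjusted p under 0.05 there were 61 higher and 105 lower probe sets, where evenly spread p would give 979. The difference between the processing sets widens the spread in this fit, so its p run large and 979 is no fair measure of chance. Other splits of the 6 arrays into 3 and 3 that part the replicate 1 arrays gave 84 to 127, against 166 for the real one.

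The other genes with the smallest p and higher values were AT1G76620, with a log2 difference of 1.56 ± 0.45, AT1G28190 with 1.51 ± 0.46, and Hop3 (AT4G12400), a co-chaperone of HSP70 and HSP90, with 0.62 ± 0.18. Those with lower values were AT3G47840 at -2.04 ± 0.54, AT3G52620 at -1.42 ± 0.40 and AT5G02670 at -1.10 ± 0.27. Several were dim in 1 group. In P-starved shoots the mean signal was 3.53 for AT5G02670, 6.77 for AT3G52620 and 11.4 for AT3G47840, and in replete shoots 3.63 for AT1G76620, 8.73 for AT3G44970 and 10.1 for AT1G28190. Hop3 was dim in both, at 12.9 and 2.70. In all 10 of these genes the P-starved and replete arrays did not overlap, and the difference had the same sign in both processing sets. The genes were picked for small p on the same arrays, which favours groups that do not overlap. Groups without overlap over all arrays must also differ the same way in both sets, so neither is independent support. For EXPA15 the log2 difference was 0.50 on the replicate 1 arrays and 1.43 on the others, and for ATSPS4F -0.86 and -2.54. Over all tested probe sets 4.25% did not overlap between the groups. Chance gives 10% only for arrays that can be exchanged, which the distance between the processing sets rules out here. In both processing sets 21.1% differed the same way without overlap within either, where 16.7% do by chance.

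**Figure D1:**
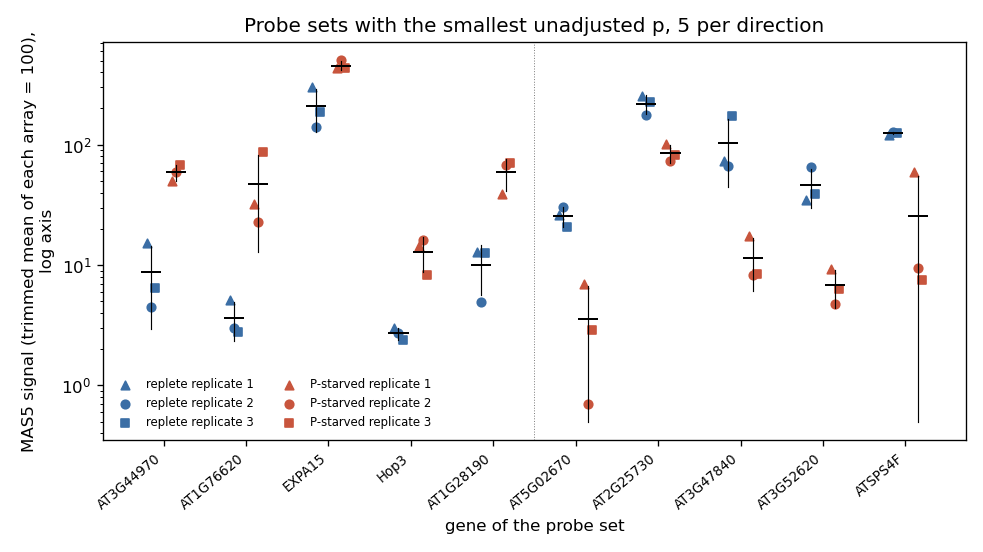
MAS5 signal on a log axis for the 10 probe sets with the smallest unadjusted p, 5 with higher values in P-starved shoots on the left and 5 with lower values on the right; symbols mark single arrays, horizontal bars the mean and vertical lines 1 SD over 3 arrays, stopped at 0.5 where they reach below it. EXPA15 lies at 454 in P-starved and 210 in replete shoots on average, and no probe set of the 10 passed the adjusted threshold.

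With the processing set as a block the median SE fell from 0.52 to 0.26, and limma still called 0 probe sets in either direction, with a smallest adjusted p of 0.788. At an unadjusted p under 0.05 there were then 530 higher and 627 lower probe sets, with the replicate number as a block 462 and 541, and on the replicate 2 and 3 arrays alone 688 and 742. Across probe sets, which are not independent replicates, the difference on the replicate 1 arrays correlated with that on the other arrays with r = 0.05 and rho = 0.05.

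The second naming rule, set after the data were seen, took genes of the brighter 50% of the probe sets that differed in the same direction in both sets. Some still lay under a signal of 16 on single arrays, such as RR23 and AT2G30730 on replete replicate 1, at 11.3 and 9.20. With higher values it gave EXPA15 again, IKU1 (AT2G35230), a regulator of seed size, with 169 ± 32.5 against 77.5 ± 6.06 and a log2 difference of 0.97, and RR23 (AT5G62120), a response regulator, with 1.06. AT2G30730 had 1.22, AT4G39720 0.86, AT4G35750 0.79, AT5G11230 0.77, AT1G45688 0.76, AT5G07960 0.68 and AT5G06630 0.68. With lower values it gave AT2G25730 and ATSPS4F again, AT5G64270, a splicing factor gene, with -1.47, AT1G16560 with -1.07, and AT5G10920, which encodes argininosuccinate lyase of arginine synthesis, with -0.84. The plastid gene atpI, for a subunit of the chloroplast ATP synthase, had -0.90, AT4G01610, a cathepsin B-like protease gene, -0.77, and AT1G69840 -0.61. AT3G03960, a subunit gene of the cytosolic chaperonin, had a signal of 81.0 ± 25.2 against 178 ± 51.3. The ribosomal protein gene AT3G02560 was also among them, at 888 ± 97.8 against 1544 ± 282, a difference of -0.78. None passed the adjusted threshold.

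Cytosolic ribosomal protein genes, which encode the protein part of the translation machinery, were the only fixed list of the 8 tested to be shifted. All 15 members measured on all arrays were lower in P-starved shoots, with a median log2 difference of -0.28 and a mean of -0.40. For this list limma's camera gave an adjusted p of 7.0e-05. The call did not hold with an estimated correlation (adjusted p = 0.150 with an estimated correlation) or under fry, limma's rotation test (adjusted p = 0.353). AT1G18540 had a signal of 234 ± 58.5 against 433 ± 41.2 and a log2 difference of -0.87 ± 0.28, AT5G35530 had -0.84 ± 0.40, AT2G20450 -0.78 ± 0.71 and AT1G27400 -0.68 ± 0.30. The value of AT2G20450 rests on 1 array, replete replicate 1 at 133. On the other arrays its signal was 7.80 to 28.4, and its difference on the replicate 2 and 3 arrays was -0.05. No member passed the threshold over all probe sets, and 0 passed when adjusted over the list alone. With the set as a block 2 did so over the list alone, AT1G18540 and AT2G01250, the second (-0.76) named after its value was seen.

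The median of the 15 listed genes was below 0 in both processing sets, and whether the sets differed was not tested. On the replicate 1 arrays 10 of 15 genes were lower, with a median of -0.24, and on the replicate 2 and 3 arrays 15 of 15, with a median of -0.36. With the set as a block the adjusted p from camera was 2.3e-06, and 0.477 with an estimated correlation. Camera lost the call without P-starved replicate 1 (adjusted p 0.258) and without replete replicate 2 (0.115), and leaving out any 1 array unbalances the sets between the groups. With the set as a block it kept the call without each of the arrays in turn, with adjusted p up to 0.0011. Without either replicate 1 array the blocked fit measures the group difference on the replicate 2 and 3 arrays alone. Those fits therefore do not test whether the list moved on the replicate 1 arrays. A further 98 cytosolic ribosomal protein genes, chosen after this result was known, had a median of -0.15, with 66 lower and 32 higher. On the replicate 1 arrays their median was 0.038, with 55 of 98 higher, and on the replicate 2 and 3 arrays -0.25, with 26 of 98 higher.

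**Figure D2:**
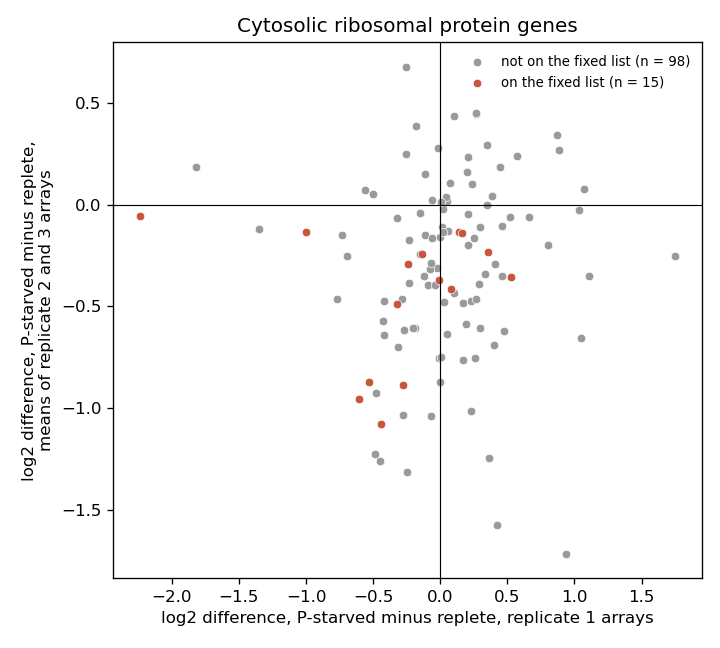
Each point is a cytosolic ribosomal protein gene, with its log2 difference (P-starved minus replete) on the replicate 1 arrays on the horizontal axis and on the replicate 2 and 3 arrays on the vertical axis. All 15 genes of the fixed list lie below 0 on the vertical axis, and 87 of the 113 genes shown do, while 53 of 113 lie below 0 on the horizontal axis.

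Of the phosphate starvation list, 1 of 40 genes was measured under its name on all 6 arrays. This was AT1G63010, which encodes a vacuolar phosphate transporter, at 325 ± 26.9 in P-starved and 356 ± 61.1 in replete shoots, a log2 difference of -0.12 ± 0.25 that was -0.45 on the replicate 1 arrays and 0.05 on the others. Another member, AT1G13750, is listed on the replicate 1 arrays alone, at 80.9 on the P-starved and 96.6 on the replete array. None of the 17 lipid remodelling genes was measured under its name, so the genes best known to respond to phosphate supply were mostly not tested by name here. Of a further list of 16 loci that phosphate starvation induces in Arabidopsis, written after the gene table had been seen, 10 were higher and 6 lower, with a median log2 difference of 0.19. Camera gave an adjusted p of 0.243 for this list, and 0.207 with the set as a block. Its members with the smallest p were AT3G44510 at 0.69 ± 0.37, AT1G67600 at 0.70 ± 0.44, AT5G20790 at 0.67 ± 0.49 and AT2G38920 at 1.01 ± 1.24, and the mean signals of the first 3 lay between 6.90 and 38.6.

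Among the enzymes that save phosphate or adenylates, 3 of 5 measured genes were higher, with a median of 0.04 (adjusted p from limma's camera 0.913). The phosphofructokinase subunit genes AT1G20950 and AT1G76550, of the pyrophosphate-dependent enzyme of glycolysis, had 0.34 ± 0.40 and 0.45 ± 0.61. Of the starch and sucrose genes, 2 of 3 were higher. Their median was 0.02, while their mean was -0.64 and camera's direction was down (adjusted p 0.154), because of ATSPS4F, the only gene of the fixed lists to pass when adjusted over the list alone. With the set as a block it passed again over the list alone. DPE1 (AT5G64860), of starch breakdown, had 0.05 ± 0.31.

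Nuclear genes of the light reactions were not shifted as a list. Of 7 measured, 3 were higher and 4 lower, with a median of -0.02 and a mean of 0.10, and camera's direction was up (adjusted p 0.913). LHCB4.1 (AT5G01530), a light-harvesting protein gene, had 1757 ± 857 against 1551 ± 834, a log2 difference of 0.21 ± 0.50, and PSBY (AT1G67740) had 0.56 ± 1.17. These SE hold the difference between the processing sets. With the set as a block they were 0.15 and 0.34, and limma's unadjusted p was 0.226 and 0.156. The Calvin cycle genes PRK (AT1G32060) and SBPASE (AT3G55800) had -0.31 ± 0.62 and -0.36 ± 0.93, and were lower in both processing sets.

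Anthocyanin and phenylpropanoid genes, whose products colour phosphate-starved leaves in many plants, were 3 higher and 3 lower. Their median was 0.03, their mean -0.03 and camera's direction down, with an adjusted p of 0.913. DFR (AT5G42800), of anthocyanin synthesis, had 108 ± 12.3 against 89.1 ± 13.3, a log2 difference of 0.24 ± 0.34, and AT4G14090 had -0.45 ± 0.72. Of the drought, cold and abscisic acid genes 3 of 5 were higher, with a median of 0.10 and an adjusted p of 0.913. The cold-regulated COR15A (AT2G42540) had 40.5 ± 20.5 against 14.4 ± 7.37 and a difference of 0.86 ± 0.49, and LTI30 (AT3G50970) had -0.25 ± 0.22. The senescence list had 1 of 3 higher, with a median of -0.04, a mean of 0.10 and camera's direction up (adjusted p 0.913), and WRKY53 (AT4G23810) had 0.44 ± 0.54. The root marker list, included as a check on root tissue, had 2 of 3 higher, with a median of 0.13 and an adjusted p of 0.913, and PYK10 (AT3G09260) had 0.27 ± 0.41.

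Lists with 1 or 2 measured genes were not tested as lists. Both glucosinolate genes were higher over all 6 arrays, with BCAT4 (AT3G19710) at 0.48 ± 0.48. The second was at 0.10 ± 0.89, and at -0.25 on the replicate 2 and 3 arrays. Both jasmonate genes were higher, THI2.1 (AT1G72260) at 0.61 ± 0.53 and the second at 0.08 ± 0.08. That second gene had mean signals of only 1.87 in P-starved and 0.93 in replete shoots. Both salicylate genes were higher, SAG101 (AT5G14930) at 0.37 ± 0.48 and the second at 0.34 ± 0.84. Both sulfate genes were lower, SIR (AT5G04590) at -0.27 ± 0.46 and the second at -0.17 ± 0.50, though at 0.44 on the replicate 1 arrays. Both reference genes were lower, PEX4 (AT5G25760) at -0.40 ± 0.53 and the second at -0.17 ± 0.34. One heat shock gene was higher, AT5G37670 at 0.28 ± 0.51, and the other was lower. Single genes stood for iron (PYE, AT3G47640, a regulator of iron homeostasis, -1.47 ± 1.12), the clock (GI, AT1G22770, -0.18 ± 0.49) and the cell cycle (PRL, AT4G02060, -0.46 ± 0.32). With the set as a block PYE passed when adjusted over the list alone, as its only member. The nitrogen, flower, xylem and epidermis lists had no gene measured under its name.

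Genes encoded in the plastid genome, with a median log2 signal of 9.93 to 12.2 per array for those of the photosynthetic complexes, made up 2 of the 8 lists written after the gene table had been seen. Genes of plastid ribosomal proteins and RNA polymerase subunits were 15 of 19 lower in P-starved shoots, with a median of -0.60 and an adjusted p from limma's camera of 8.0e-05 (adjusted p = 0.917 with an estimated correlation). Polymerase gene rpoA had 847 ± 92.1 against 1611 ± 451, a log2 difference of -0.88 ± 0.32, and rpl22 -1.75 ± 0.66, rpoC2 -1.26 ± 0.73 and rps19 -0.67 ± 0.44. Plastid genes of the photosynthetic complexes were 27 of 43 lower, with a median of -0.15, and the adjusted p was 0.243. With the set as a block it was 0.0091 (adjusted p = 0.904 with an estimated correlation), and with the replicate number as a block 0.014. Of these genes ndhH had -1.21 ± 1.00, while petN and psbM had higher values, at 0.96 ± 0.55 and 0.94 ± 0.79.

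The medians of both plastid lists were lower on the replicate 1 arrays, 1 array against 1, than on the others. That of the plastid expression genes was -1.22 there, with 1 of 19 higher, and -0.29 on the replicate 2 and 3 arrays, with 8 of 19 higher and an adjusted p of 0.522. That of the photosynthesis genes was -0.51, with 1 of 43 higher, and 0.09 with 25 of 43 higher (adjusted p 0.731). On the replicate 1 arrays the control probe set for 25S ribosomal RNA was lower in P-starved shoots as well, and on the others it was higher. Its signal was 3767 on replete replicate 1 and 881 on P-starved replicate 1, but 175 and 335 on P-starved replicates 2 and 3 and 111 and 101 on replete replicates 2 and 3. Whether the plastid lists differed between the sets was not tested.

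**Figure D3:**
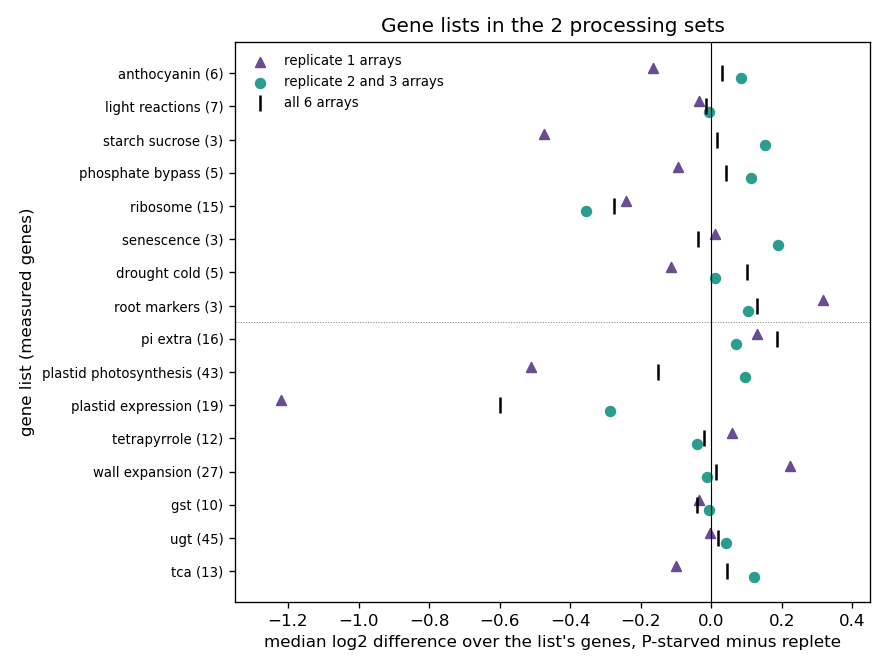
Median log2 difference (P-starved minus replete) of each gene list with 3 or more measured genes, whose number is in brackets, on the replicate 1 arrays (triangles), the replicate 2 and 3 arrays (circles) and all 6 arrays (bars); lists under the dotted line were written after the gene table had been seen. The ribosome list lies below 0 in both sets, at -0.24 and -0.36, and the plastid photosynthesis list at -0.51 and 0.09.

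The ratios of 3' over 5' signal of the actin, GAPDH and ubiquitin controls, which rise as RNA degrades, did not separate the groups. These probes were designed for Arabidopsis, and the 2 GAPDH pairs gave unlike ratios. The mean log2 ratio in P-starved and replete arrays was -3.18 and -3.40 for the first pair, and 1.82 and 1.84 for the other. With Brassica RNA the ratios may therefore not measure degradation alone. The log2 ratio differed between P-starved and replete arrays by -0.34 to 0.22 over the 6 control pairs. It differed by -0.65 to 0.028 on the replicate 1 arrays and by -0.34 to 0.66 on the others, -0.65 and 0.66 both being of the first GAPDH pair, and the test did not take the sets apart. Exact permutation p ran from 0.5 to 1, two-sided, and every Benjamini-Hochberg adjusted value was 1, where 3 arrays against 3 cannot give an exact p below 0.1.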

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

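All values in this part come from tests chosen after the data were seen. Among the 3168 probe sets listed on the replicate 1 arrays alone, which no fit above used, 8 had a signal of 100 or more and were 4-fold or more higher on the P-starved array, and 9 were as far the other way. These counts lie outside the fits and come from 1 array against 1 with no replicate check. They make up 0.25% and 0.28% of these probe sets, against 0.34% and 0.48% of those listed on all arrays. Among the 19578 probe sets listed on all arrays, 66 and 93 met the same limits on the replicate 1 arrays, and Fisher's exact test of the share with higher values between the 2 kinds of probe set gave a two-sided p of 0.612. The highest ratio with a gene name was that of AT3G43690, at 104 against 7.10. No biological explanation was tested.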

How the results depend on the processing

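The count of probe sets past the threshold was 0 in both directions in every fit run, including those without each of the 6 arrays. The fits with the processing set or on the replicate 2 and 3 arrays alone, and scaling over the shared probe sets, were chosen after seeing the data. With the replicate number as a block (replicate block) the count was also 0, and that block changed no call of a fixed list. The number of fixed lists shifted was 1, and it was 0 with an estimated correlation and 0 under fry, with and without the processing-set block. Without each array in turn it ranged from 0 to 2: it was 0 without P-starved replicate 1 and without replete replicate 2, and 2 without P-starved replicate 2. The ribosomal list kept its direction in all 30 alternatives, with a median of -0.59 to -0.18 and an adjusted p of 2.3e-06 to 0.477, and passed in 24. These are not independent checks. Camera does not use the eBayes settings, and the deposited values were already on the scale used, so those alternatives repeat the main result. The replicate 2 and 3 arrays alone and the blocked fits without either replicate 1 array make 1 comparison, with a median of -0.36. The list failed with an estimated correlation and under fry, with and without the set block. Leaving out an array unbalances the processing sets between the groups. The cause of the reversals given below was not tested. No scaling reversed a list or a named gene, and low signal limits what can be said of dim genes.

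Camera's direction reversed for lists that were not past the threshold in the main fit, here with their median log2 difference. Anthocyanin genes had 0.031 with the replicate block and the processing-set block, 0.085 on the replicate 2 and 3 arrays, and -0.045 in the brighter 50% of the probe sets, with and without the set block. Phosphate bypass genes had 0.043 with either block and 0.11 on the replicate 2 and 3 arrays, and UDP-glycosyltransferases 0.020 with either block and 0.011 with offset 4. In the brighter 50%, with and without the set block, phosphate starvation loci had -0.043 and citrate cycle genes -0.048, with fewer genes tested. On the replicate 2 and 3 arrays root markers had 0.10, cell wall genes -0.012 and plastid photosynthesis genes 0.095, the last also with the set block without either replicate 1 array, although with all arrays that block put it past the threshold in the other direction (adjusted p 0.0091). Glutathione S-transferases had -0.042 under fry. Genes that reversed on the replicate 2 and 3 arrays were AT1G63010 (0.052), AT4G14090 (0.077), AT5G37670 (-0.019) and GI (0.19).

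Without each array in turn, medians of lists that reversed at least once ranged from -0.17 to 0.11 for anthocyanin, -0.31 to 0.61 for light reactions, -0.036 to 0.26 for the phosphate bypass, -0.15 to 0.44 for senescence, -0.26 to 0.30 for drought and cold, -0.12 to 0.38 for root markers, -0.28 to 0.052 for chlorophyll and haem, -0.057 to 0.23 for cell wall genes, -0.16 to 0.19 for glutathione S-transferases, -0.0048 to 0.057 for UDP-glycosyltransferases and 0.0046 to 0.15 for the citrate cycle. Plastid photosynthesis genes ranged from -0.46 to 0.16, and without replete replicate 1 they passed in the other direction (adjusted p from limma 0.0204). Log2 differences ranged from -2.07 to 0.077 for AT1G16560, -0.20 to 0.014 for AT1G63010, -0.31 to 1.76 for PSBY, -0.16 to 0.61 for LHCB4.1, -0.73 to 0.27 for PRK, -1.14 to 0.52 for SBPASE, -0.19 to 0.26 for DPE1, -0.64 to 0.11 for SIR, -0.052 to 0.70 for AT5G37670, -0.48 to 0.29 for GI and -0.80 to 0.11 for PEX4.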

Other observations

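The tests of 1 processing set, of RNA without poly(A) tails, of the hybridisation and of other probes, and the check of probe set pairs within the sets, were chosen only after related results had been seen; the splits, the matched random lists and the comparison of 2 probe sets of one gene were written down before their results. Of the other lists written after the gene table had been seen, cell wall genes (expansins and xyloglucan endotransglucosylases) were 14 of 27 higher, with a median of 0.01 and an adjusted p from limma's camera of 0.767. EXPA21 (AT5G39260) had a log2 difference of 0.83 ± 0.54. Chlorophyll and haem synthesis genes were 8 of 12 lower, with a median of -0.02, a mean of -0.16 and an adjusted p of 0.243. Of these, hemb2 (AT1G44318) had -0.86 ± 0.52 and PORB (AT4G27440), which makes chlorophyllide, 1974 ± 364 against 2370 ± 558. Glutathione S-transferase genes were 5 of 10 higher (median -0.04, adjusted p 0.984), UDP-glycosyltransferase genes 26 of 45 (0.02, 0.984) and citrate cycle genes 7 of 13 (0.04, 0.984), the last with a mean of -0.02. The 16 phosphate starvation loci passed the threshold in 1 of 6 fits with the set as a block that left out 1 array (adjusted p 0.0325 to 0.917).

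The lower values of cytosolic ribosomal protein genes could be a shift shared by all genes of the same brightness, which is argued against, though not firmly, by the list's median of -0.28 at percentile 1.12 of 10000 random lists matched on mean level (percentile 6.33 on the replicate 1 arrays, 0.38 on the others). For the replicate 2 and 3 arrays, the 98 further genes argue in the same way against a shift peculiar to the 15 listed genes. Their median was -0.15 at percentile 0.01, the smallest that 10000 lists can give. It was -0.25 at percentile 0.01 on the replicate 2 and 3 arrays, but 0.038 at percentile 78.6 on the replicate 1 arrays. On the replicate 1 arrays that explanation stays open. All these random lists leave out the correlation between genes, and with it estimated limma's camera gave the 98 genes an unadjusted p of 0.0478, and of 0.203 with the set as a block, and fry gave 0.183 and 0.200. That it comes from 1 processing set stays open, because over all 113 genes the median was -0.25 on the replicate 2 and 3 arrays, at percentile 0.01, but 0.02 on the replicate 1 arrays, at percentile 68.4. A lower level of these transcripts under phosphate starvation therefore may hold for the replicate 2 and 3 plants, as a hypothesis that 1 array against 1 in the other set neither bears out nor excludes.

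The lower values of plastid-encoded genes were weighed against carry-over of RNA without poly(A) tails, of which the 25S ribosomal RNA control, a single probe set, served as the measure. On the replicate 1 arrays, where the control was lower in P-starved shoots (log2 difference -2.08), the median was -0.51 for the photosynthesis genes and -1.22 for the expression genes. On the replicate 2 and 3 arrays, where the control was higher (1.09), 25 of 43 photosynthesis genes and 8 of 19 expression genes were higher, which decides nothing for either (two-sided exact binomial p = 0.360 and 0.648, asked to be under 0.05 only after the counts were seen). Carry-over and a change in plastid transcript levels in the replicate 1 plants both stay open.

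The distance between the processing sets was weighed against 3 explanations. Another array hybridisation or scan that acts on spike-ins and plant transcripts alike is argued against as the whole cause. The log2 difference between the sets had an SD of 0.195 over the 18 spike-in probe sets, which come from few transcripts. Over 3715 plant probe sets of like brightness it was 1.27 (one-sided permutation p = 0.0001 for the ratio, the smallest that 10000 resamples can give). The spike-ins match their probes, while Brassica transcripts may not. A hybridisation difference that moves only mismatched transcripts therefore stays open. Other RNA content of the replicate 1 plants was to be excluded by a low correlation between 2 probe sets of one gene in their log2 difference between the sets. This was r = 0.068 over 92 genes (95% bootstrap interval -0.12 to 0.27, below the limit of 0.3 set beforehand). That limit excludes nothing here, because nothing shows that such pairs follow one transcript: within the sets they correlated in level with only 0.19 and 0.18, and in the group difference with 0.13 and -0.10. Other RNA content, other probes used for each probe set (the same 92 genes), which no label states, and a hybridisation difference of mismatched transcripts therefore cannot be told apart.

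The 6 arrays were also split into 3 and 3 in all 10 ways. For the count of probe sets past the threshold this decides nothing, because no split can give fewer than the real count of 0. All 10 gave at least that count, and the highest other gave 4. That split kept the replicate 1 arrays together, as did 3 others, and these 4 gave between 3327 and 3612 probe sets at an unadjusted p under 0.05 against 166 for the real one, which points to the processing sets as a structure of the samples. The 5 other splits that part the replicate 1 arrays gave 84 to 127 in that fit, and with the set as a block 599 to 855 against 1157 for the real one. The split with 127 and 855 only exchanges the 2 replicate 1 arrays between the groups. It keeps the P-starved against replete comparison on the replicate 2 and 3 arrays. For the gene lists, 4 of the 10 splits shifted as many lists as the real one, which shifted 1, and the highest other also shifted 1. In the 3 other splits the list was also the ribosomal one, with a median of 0.37, 0.30 and 0.24 regardless of sign, against 0.28 for the real split. The adjusted p from limma's camera was 0.0484, 0.0167 and 0.0397, against 7.0e-05. The splits with 0.37 and 0.30 kept the replicate 1 arrays together, so they also measure the distance between the processing sets. The split with 0.24 is the one that only exchanges the replicate 1 arrays. It keeps the real comparison on the replicate 2 and 3 arrays, where all 15 listed genes were lower. It therefore does not show how far the list moves without a group difference. In the remaining splits that part the replicate 1 arrays the median was 0.019 to 0.086. Of the 4 splits that part all 3 replicate numbers, 2 shifted 1 list, the real one and that with 0.24. None called a probe set. With 10 splits no share can fall under 0.05.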
